A study of Homo sapiens with 6 samples.

How the data were processed

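Total RNA levels of K562 and K562R cells were measured on Clariom S arrays, 3 samples of each line and 1 array per sample, grouped by the sample titles. The deposited values are log2 signals per transcript cluster, on a scale that is comparable between arrays by its distribution. The method of summarisation and normalization is not given in the sources used here. MAS5 is named per the submitters' processing notes, with no role stated. The base of the logarithm is not stated either. Base 2 was taken as the usual base for such arrays, and the values do not settle it: the largest, 19.42, exceeds what a 16-bit scanner records even in base 2. All log2 differences and folds rest on that reading. The deposited annotated table and the deposited series values were checked against each other and differed in 0 rows. There were no detection calls, no scan dates and no batch labels.

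Of 21447 transcript clusters with values, 19489 carried 1 Entrez ID and 1 symbol, and 19455 of these matched by Entrez ID in the RefSeq gene table of assembly GRCh38.p14, which updated 1082 symbols. That table served for names and for the order of neighbouring genes, which was set by its start coordinates. The other clusters, 1013 with no Entrez ID and 945 with several IDs or symbols, were kept out of the gene test because they do not stand for 1 gene. The values of 1 transcript cluster were not available. Where a gene had several clusters (490 genes), the cluster with the highest mean over all 6 arrays was used, which left 18576 genes. No filter on dim genes was applied. With no detection calls, the 95th percentile of 375 olfactory receptor genes, 5.85, stands for background. This choice was made after the data were seen. Folds of genes near that level are compressed.

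The lines were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings; statmod 1.5.0 was installed beside it). The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p under 0.05. A size threshold of 2-fold was fixed beforehand. Values are means ± SD over the 3 arrays of a line, and differences are K562R minus K562 on the log2 scale ± SE. There were 30 gene lists with at least 5 measured members, fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, with fry beside it. Camera with a correlation estimated per list was an alternative. All p-values in the text come from limma.

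The genes named were set by a rule fixed before the data were examined. It takes the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05. Their lines must not overlap and the higher mean must lie above the median of all genes, 6.24. It adds ANGPT1, TEK, JAK2, STAT5A and STAT5B whatever their result, and up to 2 risen and 2 fallen members of each list with the largest differences. Where no member passed, it takes the member with the largest difference. Other genes are marked in the text as chosen after their values were seen.

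The alternatives were quantile normalization, centring of each array on its median, a filter at the 30th percentile of mean signal, the series values, the mean of a gene's clusters, trend and robust eBayes, array weights, the replicate number as a block, a floor at the 10th percentile, and each array left out in turn. A stricter threshold of 0.01, sizes of 1.5-fold and 4-fold, camera on ranks and camera with estimated correlation were added to these before the data were examined. Counting all clusters with 1 symbol as genes was added after the data were seen. The same fit was also run on the 10 splits of the 6 arrays into 3 and 3.

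The procedure was tested on simulated data for the comparison of K562R with K562, with 18576 genes and 50 changed genes per size. It recovered 6% of genes changed by 0.5 on the log2 scale, 64% of those changed by 1, and 100% of those changed by 2 or 4, with 14 false calls among 149. Of 5 simulated lists of 25 genes shifted by 0.5, camera called 5, and of 20 unshifted lists it called 1. The simulated genes were drawn independently of each other, unlike genes of the real lists. The estimated correlation was 0.118 in the megakaryocyte list and 0.121 in the adhesion list, for example. The simulation therefore cannot test the preset correlation or the share of false calls among real lists. The simulation had 149 calls in all against 3035 in the data, so its adjusted threshold was stricter. The shares recovered therefore do not give the sensitivity of the real comparison, in which changes below 2-fold may still be missed.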

Results

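Messenger RNA levels were measured on Clariom S arrays in 2 human chronic myeloid leukaemia cell lines. K562 is an established line that carries the BCR-ABL fusion and is sensitive to tyrosine kinase inhibitors (TKI), the drugs that block the BCR-ABL kinase. K562R is a multidrug-resistant line derived from K562, which the series design describes as free of mutations in the BCR-ABL region. Each line was represented by 3 samples, 1 array per sample, and the labels mark the K562 samples as grown without drug. Nothing in the sources used here says which drug K562R was selected with or whether drug was present at harvest. A direct effect of drug therefore cannot be told apart from a lasting difference between the lines. The array medians lay between 5.99 and 6.10 on the log2 scale over 21447 transcript clusters. Between arrays of the same line, Pearson's r across genes was 0.986 to 0.992, and between lines 0.956 to 0.964. The first principal component held 68.0% of the variance and separated the lines. The labels do not say whether the 3 samples of a line came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

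The comparison of the lines asks which transcripts differ between a resistant line and its drug-sensitive parent. K562R and K562 differed in 3035 of 18576 genes (16.3%) by limma's moderated test at an adjusted p under 0.05, with 1495 genes higher and 1540 lower in K562R. At an unadjusted p under 0.05 there were 5151 genes, and in 31.9% of genes the values of the lines did not overlap, against 10% by chance for 3 arrays against 3. Of the 3035 genes past the adjusted threshold, 1753 differed at least 2-fold, 903 higher and 850 lower, and 80 differed at least 16-fold, 53 higher and 27 lower. The largest rise was that of NTS, which encodes the peptide neurotensin, from a log2 signal of 4.80 ± 0.50 in K562 to 13.30 ± 0.32 in K562R (SD, n = 3 each; limma adjusted p = 8.37e-08). AHR, a ligand-activated transcription factor, rose by 7.46 ± 0.40 on the log2 scale (SE). ITGA2B, the integrin alpha chain of platelets, rose by 7.33 ± 0.24, and LPCAT2, an enzyme of phospholipid remodelling, by 7.17 ± 0.25. LCP2 and TESPA1, which take part in signalling from immune receptors, rose by 7.15 ± 0.33 and 6.62 ± 0.30. CD44, a receptor for hyaluronan, rose by 6.38 ± 0.30. Metallothioneins are proteins that bind zinc and copper. The metallothionein genes MT2A, MT1L and MT1X, of which MT1L is annotated as non-coding, rose by 6.84 ± 0.70, 6.41 ± 0.83 and 6.17 ± 0.76. Their spread between the K562R arrays was wide, with SDs of 1.83, 2.22 and 1.97, because K562R replicate 3 lay below the other 2 arrays. MT2A, for instance, had 16.89, 16.75 and 13.65. Without K562R replicate 3 the rises were 7.90, 7.68 and 7.30, and without K562R replicate 1 those of MT1L and MT1X were 5.68 and 5.50. PRSS2, a trypsinogen, and SSX4B, a cancer-testis antigen, rose by 6.76 ± 0.28 and 6.58 ± 0.42. The MT1, PRSS2 and SSX4B probes face near-identical paralogs, so which copy gave the signal is uncertain.

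The largest fall was that of CCND2, which encodes cyclin D2, from 15.66 ± 0.27 to 8.62 ± 0.11 (SD, n = 3 each; limma adjusted p = 5.91e-08). OR51B5, an olfactory receptor gene beside the beta-globin cluster on chromosome 11, fell by 7.02 ± 0.32 on the log2 scale (SE), and FAM178B by 6.65 ± 0.43. The X-linked cancer-testis genes CT45A10, CT45A8, CT45A9 and CT45A2 fell by 6.51 ± 0.28, 5.98 ± 0.35, 5.98 ± 0.35 and 5.95 ± 0.35. These copies are nearly identical, and CT45A8 and CT45A9 had the same values on all arrays, so they are not separate measurements. SCG3 fell by 5.68 ± 0.28, IL23R, a cytokine receptor chain, by 5.66 ± 0.29, and SERPINF1 by 5.56 ± 0.31. RELN, which encodes the secreted protein reelin, fell by 5.21 ± 0.42, with a difference of -5.82 without K562R replicate 3, and ZDHHC2, a palmitoyltransferase, by 5.15 ± 0.41. Of the 80 genes at least 16-fold apart, 52 had a mean in the lower line below 5.85, the 95th percentile of 375 olfactory receptor genes, which stands here for background. Folds of such genes are compressed by background.

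The genes named in the series title concern angiopoietin-1 and the JAK and STAT5 proteins, and the question they address is whether this pathway accompanies resistance. ANGPT1, which encodes angiopoietin-1, was 2.40-fold higher in K562R, with log2 signals of 8.62 ± 0.24 in K562 and 9.88 ± 0.19 in K562R (SD, n = 3 each; limma adjusted p = 0.00156). TEK, which encodes its receptor Tie2, had signals of 4.19 ± 0.16 and 3.91 ± 0.44, both below the level taken as background (limma adjusted p = 0.517). JAK2, the kinase that signals from many cytokine receptors, fell 4.73-fold, from 9.51 ± 0.30 to 7.27 ± 0.26 (limma adjusted p = 7.27e-05). It lies on chromosome 9 between WASHC1 and NOL6, in a stretch of 48 neighbouring genes above background in either line. Of these, JAK2 included, 33 were lower in K562R, with a median log2 difference of -0.58. Whether the fall of JAK2 is part of a regional difference was not tested. STAT5A rose by 0.81 ± 0.18 on the log2 scale (SE; limma adjusted p = 0.0105). STAT5B had signals of 11.15 ± 0.35 and 11.24 ± 0.38 (limma adjusted p = 0.869). The study may have chosen ANGPT1 and this pathway on the same samples, so their values are not independent evidence.

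**Figure D1:**
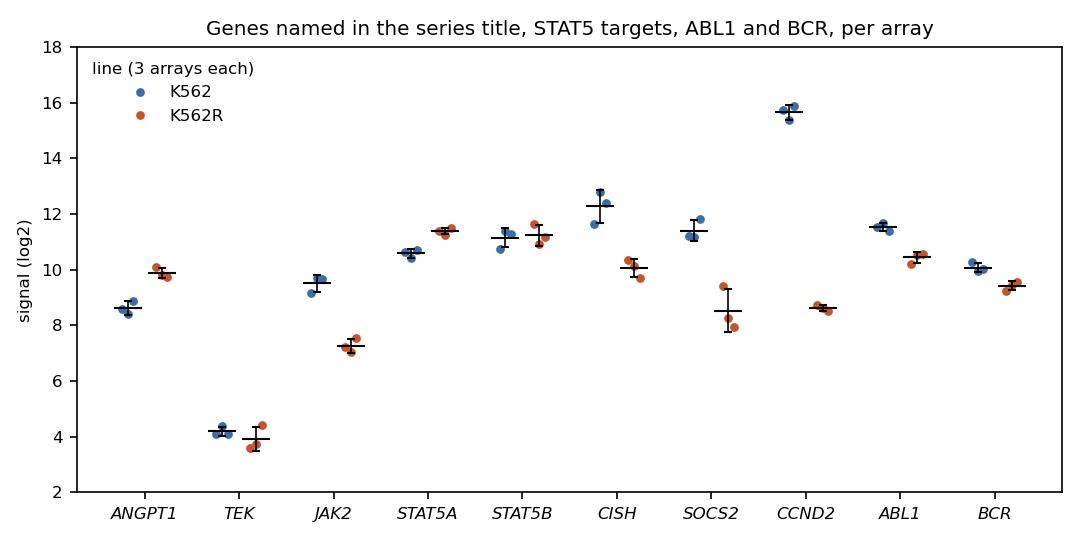
Log2 signal (vertical axis) of 10 genes on each of the 6 arrays, 3 K562 (blue) and 3 K562R (orange), with the mean (black bar) and SD (whiskers) of each line. ANGPT1 is higher by 1.26 and CCND2 lower by 7.04 on the log2 scale in K562R, while the STAT5B arrays of the lines overlap; CISH, ABL1 and BCR were added after their values were seen.

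Of the 20 measured genes of the angiopoietin and Tie list, 3 rose and 0 fell, and 3 when adjusted over the list alone. Among them PTPRB, a phosphatase that acts on Tie2, rose by 3.23 ± 0.20 on the log2 scale (SE). The JAK, STAT and receptor list had 6 risen and 1 fallen of 26, and 9 past the threshold when adjusted over the list alone. IL6ST, the shared receptor chain gp130, rose by 2.55 ± 0.20, and IL2RG, the common gamma chain, by 2.49 ± 0.21. Of 23 STAT5 target genes, 3 rose and 5 fell, and 10 passed when adjusted over the list alone. CCND1 rose by 3.72 ± 0.32 and CDKN1A, a cell cycle inhibitor, by 1.77 ± 0.26, while CCND2 fell by 7.04 ± 0.19 and SOCS2, a feedback inhibitor of cytokine signalling, fell by 2.87 ± 0.35. CISH, another STAT5-driven inhibitor, chosen after its values were seen, fell by 2.21 ± 0.29. As a set, none of these 3 lists passed limma's camera test, with adjusted p = 0.252, 0.0513 and 0.620. By fry they did pass, with adjusted p = 0.00639, 0.0148 and 0.0164. The JAK and STAT list did pass camera without K562 replicate 3, with a camera adjusted p of 0.0334 (adjusted p = 0.541 with an estimated correlation on all arrays). The members of these 3 lists were fixed before the data were examined, but the study may have chosen the pathway they cover on these samples.

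Among 19 measured drug transporters, 4 rose and 2 fell, and 8 passed when adjusted over the list alone (camera adjusted p = 0.356). The uptake carrier SLCO3A1 rose by 3.47 ± 0.48 on the log2 scale, or 4.14 without K562R replicate 3, and the efflux pump ABCC5 by 1.92 ± 0.23 (SE). ABCG2, an efflux pump, fell by 0.91 ± 0.24, from 5.91 ± 0.46 to 5.00 ± 0.15, close to background in both lines. That call rested on single arrays, with a limma adjusted p of 0.101 when K562 replicate 3 was left out, and 0.0542, 0.0915 and 0.0647 without K562 replicate 1, K562R replicate 2 and K562R replicate 3. The carrier SLCO1A2 fell by 1.56 ± 0.37, with an adjusted p of 0.0606 without K562 replicate 2 and 0.0643 without K562 replicate 3. The list had 0 falls without K562 replicate 3, and 1 without K562 replicate 1, K562 replicate 2, K562R replicate 2 or K562R replicate 3. ABCB1, the P-glycoprotein gene, and ABCC4 were chosen after their values were seen. ABCC4 rose by 1.24 ± 0.20. ABCB1 had signals of 5.32 ± 0.36 and 6.12 ± 0.12 (SD), close to background. Its limma adjusted p was 0.0281 with all arrays, 0.0139 without K562 replicate 3, and 0.0536 to 0.0959 without each of the other 5 arrays.

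Of 29 genes for BCR-ABL, its partners and Src family kinases, 6 rose and 6 fell, and 12 passed when adjusted over the list alone (camera adjusted p = 0.812). The receptor kinase KIT rose by 3.70 ± 0.32 on the log2 scale and SYK by 2.59 ± 0.24 (SE). FGF2, a growth factor, fell by 2.22 ± 0.25, and its receptor FGFR1 fell by 1.20 ± 0.19. FGFR1 was at the background level in K562 (5.87 ± 0.28, SD) and below it in K562R, and SYK was near it in K562R (5.92 ± 0.29), so the sizes of these differences are uncertain. ABL1 and BCR, chosen after their values were seen, fell by 1.09 ± 0.18 and 0.66 ± 0.18. The array probes cannot tell the fusion transcript from the unfused genes. The ABL1 call held with each array left out. The BCR call (limma adjusted p = 0.0331) did not: its adjusted p was 0.0821, 0.0567 and 0.0838 without K562 replicates 1, 2 and 3, 0.0837 and 0.0515 without K562R replicates 2 and 3, and highest without K562R replicate 1.

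Of the 30 gene lists, 3 were shifted up in K562R and 3 down by camera with a preset correlation of 0.01 between genes. Splits of the 6 arrays into 3 and 3 that mix the lines gave 1 to 5 such lists each. Megakaryocyte and platelet genes moved up, with 9 risen and 0 fallen of 26 and 11 past the threshold when adjusted over the list alone (camera adjusted p = 0.000429; adjusted p = 0.541 with an estimated correlation). ITGA2B led them, followed by THBS1, which encodes thrombospondin-1 and rose by 4.49 ± 0.34 on the log2 scale (SE). Members named after their values were seen were CD9 and the integrin chain ITGB3, which rose by 3.25 ± 0.25 and 2.57 ± 0.32. Feedback and immediate early genes of the ERK pathway had 10 risen and 0 fallen of 23, and 11 passed when adjusted over the list alone (camera adjusted p = 0.000884; adjusted p = 0.453 with an estimated correlation). There was 1 fall without K562R replicate 3. SPRY1, an inhibitor of receptor kinase signalling, rose by 4.29 ± 0.24 and CCND1, as above, by 3.72 ± 0.32. SPRY4 and EGR1, named after their values were seen, rose by 2.37 ± 0.24 and 2.38 ± 0.32. Adhesion, integrin and matrix genes had 9 risen and 2 fallen of 28, and 12 passed when adjusted over the list alone (camera adjusted p = 0.00521; adjusted p = 0.541 with an estimated correlation). CD44 led the rises and LAMB1, a laminin chain, rose by 3.65 ± 0.24, while VIM, which encodes vimentin, fell by 1.11 ± 0.23. FN1, fibronectin, fell by 1.57 ± 0.43 from a K562 signal of 6.03 ± 0.80, near background, with limma adjusted p = 0.102, 0.119, 0.0715 and 0.108 without K562 replicate 2, K562 replicate 3, K562R replicate 1 and K562R replicate 2, each of which left 1 fall in the list.

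Cholesterol synthesis genes moved down, with 1 risen and 10 fallen of 21 and 12 past the threshold when adjusted over the list alone (camera adjusted p = 0.00034; adjusted p = 0.453 with an estimated correlation). FDFT1, which encodes squalene synthase, fell by 2.36 ± 0.31 on the log2 scale and MSMO1 fell by 2.24 ± 0.47 (SE). IDI1 and NSDHL, chosen after their values were seen, fell by 1.74 ± 0.19 and 1.60 ± 0.22. SQLE, squalene epoxidase, went the other way and rose by 2.29 ± 0.22. Ribosomal protein genes had 1 risen and 8 fallen of 24, and 10 passed when adjusted over the list alone (camera adjusted p = 0.000429; adjusted p = 0.453 with an estimated correlation). RPL18 fell by 1.07 ± 0.17 on the log2 scale. The 1 rise, RPS12 at 0.58 ± 0.17, did not pass when any of the 6 arrays was left out: its limma adjusted p was 0.0815, 0.113 and 0.117 without K562 replicates 1, 2 and 3, and 0.134, 0.0708 and 0.0972 without K562R replicates 1, 2 and 3. NRF2, glutathione and redox genes had 3 risen and 10 fallen of 38, and 14 passed when adjusted over the list alone (camera adjusted p = 0.0219; adjusted p = 0.541 with an estimated correlation). ME1, which supplies NADPH, fell by 2.01 ± 0.33, and NQO1, chosen after its values were seen, fell by 1.49 ± 0.25. GSTM3 rose by 1.64 ± 0.29. Without K562R replicate 2 the list had 6 fallen members and a camera adjusted p of 0.0969.

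**Figure D2:**
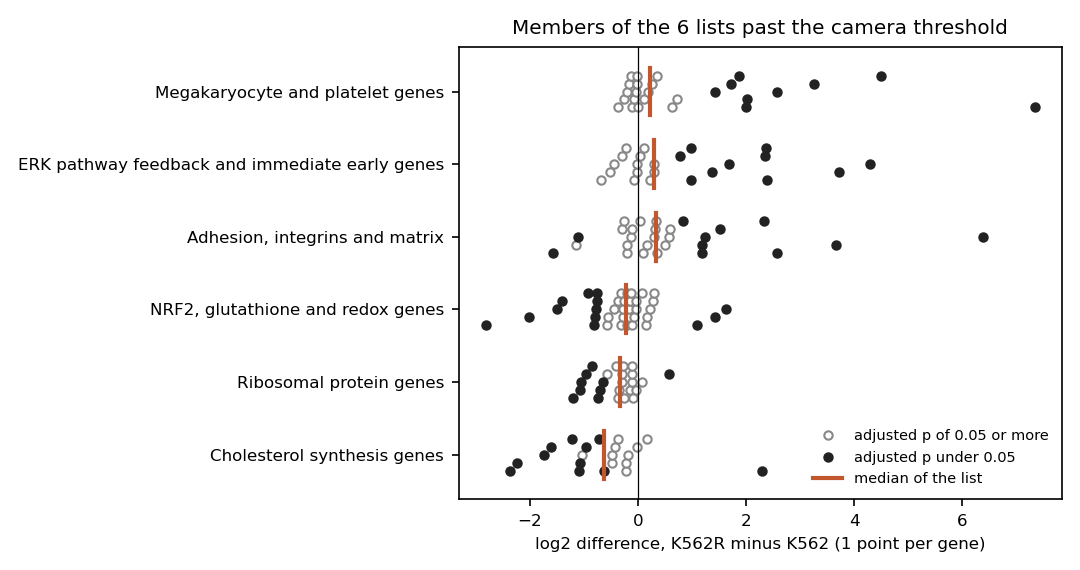
Log2 difference of K562R minus K562 (horizontal axis, 1 point per gene) for the measured members of the 6 lists past the camera threshold; filled points have a limma adjusted p under 0.05 and the orange bar is the list's median. The medians of the megakaryocyte, ERK feedback and adhesion lists are 0.22, 0.30 and 0.33, and those of the NRF2, ribosomal protein and cholesterol lists are -0.22, -0.32 and -0.63.

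With a correlation estimated from the data, 0 lists passed camera, and 3 had an unadjusted p under 0.05. A higher correlation does not account for all of this. The ERK list's estimate, 0.00537, lay below the preset 0.01, yet its unadjusted camera p rose from 0.000118 to 0.0158. The other lists past the threshold had estimates of 0.0397 to 0.121. The change therefore cannot be read as an effect of correlation between genes alone. With an estimated correlation, camera takes its degrees of freedom from the 6 arrays, and with a preset correlation from the number of genes. The estimated setting is therefore stricter even at an equal correlation. By fry, which asks only whether the genes of a list changed, 14 lists changed on balance in 1 direction and 28 in either direction.

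Haemoglobin and erythroid genes went both ways, with 7 risen and 8 fallen of 35, and 19 past the threshold when adjusted over the list alone (camera adjusted p = 0.915). HBE1, embryonic epsilon-globin, rose from 11.99 ± 0.23 to 17.77 ± 0.20 (SD, n = 3 each; limma adjusted p = 1.01e-07). CA1, carbonic anhydrase 1, rose by 5.78 ± 0.20 on the log2 scale (SE). AHSP, the chaperone of alpha-globin, fell by 3.19 ± 0.23. The count of fallen erythroid genes was 5 without K562 replicate 1 and 4 without each of K562 replicate 2, K562R replicate 1 and K562R replicate 2. It was 7 without K562 replicate 3 and 10 without K562R replicate 3, and the camera direction turned down in each of these cases. Stem and progenitor cell genes had 5 risen and 2 fallen of 21, and 9 passed when adjusted over the list alone (camera adjusted p = 0.406). KIT and CD44 were the largest rises, and ALDH1A1, a retinaldehyde dehydrogenase, and IL1RAP, a receptor chain, fell by 3.21 ± 0.25 and 1.56 ± 0.32. Signalling genes of the WNT, beta-catenin and TGF-beta pathways had 10 risen and 4 fallen of 32, and 16 passed when adjusted over the list alone (camera adjusted p = 0.203). ID2 and the receptor TGFBR2 rose by 4.32 ± 0.25 and 3.11 ± 0.19, and the co-receptor TGFBR3 and LEF1 fell by 4.72 ± 0.25 and 2.17 ± 0.23.

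Interferon response genes had 8 risen and 3 fallen of 35, and 14 passed when adjusted over the list alone (camera adjusted p = 0.200). PSMB8, an immunoproteasome subunit, and HERC5 rose by 3.32 ± 0.22 and 3.16 ± 0.25 on the log2 scale (SE), and BST2 and IFITM1 fell by 4.19 ± 0.21 and 2.44 ± 0.24. Antigen presentation genes had 4 risen and 1 fallen of 19, and 5 passed when adjusted over the list alone (camera adjusted p = 0.620). HLA-B rose by 1.24 ± 0.23 and B2M, the light chain of the same complex, fell by 2.08 ± 0.24. The count of risen members was 1 without K562 replicate 1, K562R replicate 2 or K562R replicate 3, and 2 without K562 replicate 2 or 3. NF-kB target and cytokine genes had 4 risen and 2 fallen of 25, and 8 passed when adjusted over the list alone (camera adjusted p = 0.356). The chemokine CCL2 and the feedback inhibitor TNFAIP3 rose by 2.87 ± 0.48 (2.16 without K562R replicate 3) and 1.91 ± 0.38, and IL18 fell by 3.66 ± 0.36. IL18 was the 1 fall left without K562 replicate 1 or 3 or without K562R replicate 1, 2 or 3. The NF-kB list had 6 rises without K562R replicate 2. Apoptosis regulators had 2 risen and 4 fallen of 29, and 7 passed when adjusted over the list alone (camera adjusted p = 0.972). CFLAR, an inhibitor of caspase-8, and CASP8 itself rose by 2.34 ± 0.22 and 1.34 ± 0.23, and the survival genes BCL2 and XIAP fell by 1.95 ± 0.33 and 1.48 ± 0.17. BCL2 was near background in K562 (5.95 ± 0.73, SD).

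Drug metabolism enzymes had 2 risen and 3 fallen of 21, and 6 passed when adjusted over the list alone (camera adjusted p = 0.596). ALDH1A2 rose by 1.46 ± 0.18 on the log2 scale (SE) and was the 1 rise left without K562 replicate 3 or K562R replicate 3, and EPHX1 fell by 2.42 ± 0.26. Genes of the integrated stress and unfolded protein responses had 1 risen and 3 fallen of 24, and 4 passed when adjusted over the list alone (camera adjusted p = 0.914). PSAT1 and PDIA4 fell by 1.81 ± 0.40 and 1.78 ± 0.23. There were 5 falls without K562R replicate 1. The rises numbered 0 without K562 replicate 1, K562 replicate 2, K562R replicate 1 or K562R replicate 3, and 2 without K562R replicate 2. Heat shock and chaperone genes had 4 risen and 0 fallen of 13, and 10 passed when adjusted over the list alone (camera adjusted p = 0.131). The count of rises was 6 without K562 replicate 1, 1 without K562 replicate 2 or 3 and 2 without K562R replicate 3. There were 2 falls without K562R replicate 1. Without K562 replicate 1 the list passed, with a camera adjusted p of 0.0264 (adjusted p = 0.541 with an estimated correlation on all arrays). Hypoxia and glycolysis genes had 2 risen and 1 fallen of 29, and 3 passed when adjusted over the list alone (camera adjusted p = 0.869). The glucose carrier SLC2A1 and PFKP rose by 1.98 ± 0.19 and 0.80 ± 0.17, and LDHB fell by 0.93 ± 0.20. There were 3 falls without K562 replicate 1 and 2 without K562R replicate 1. Autophagy and lysosome genes had 5 risen and 4 fallen of 27, and 13 passed when adjusted over the list alone (camera adjusted p = 0.849). ATG7 rose 4.20-fold and ATG9A rose by 1.13 ± 0.18, and 2 falls were left without K562 replicate 2 or K562R replicate 2.

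The G1/S and replication list had 5 risen and 2 fallen of 30, and 8 passed when adjusted over the list alone (camera adjusted p = 0.131). RFC4 and MCM3 rose by 1.20 ± 0.17 and 1.15 ± 0.20 on the log2 scale (SE). There were 3 rises under centring, 2 without K562 replicate 2 or 3 or without K562R replicate 1 or 3, and 3 without K562R replicate 2. The falls numbered 1 without K562 replicate 1 or 2, and 0 without K562 replicate 3, K562R replicate 2 or K562R replicate 3. Without K562 replicate 1 the list passed, with a camera adjusted p of 0.00456 (adjusted p = 0.789 with an estimated correlation on all arrays). The G2/M and mitosis list had 7 risen and 0 fallen of 30, and 8 passed when adjusted over the list alone (camera adjusted p = 0.131). BUB1 and KIF2C rose by 1.36 ± 0.26 and 0.86 ± 0.18. There were 4 rises without K562 replicate 2, K562 replicate 3 or K562R replicate 3, and 3 without K562R replicate 1 or 2, and 1 fall without K562R replicate 1. DNA repair genes had 5 risen and 5 fallen of 32, and 13 passed when adjusted over the list alone (camera adjusted p = 0.849). FANCA and XRCC5 rose by 1.47 ± 0.18 and 1.05 ± 0.21, and RAD51C and ERCC2 fell by 1.48 ± 0.27 and 1.19 ± 0.22. There were 3 rises and 3 falls without K562 replicate 3, and 3 rises without K562R replicate 2.

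Markers of lymphocytes, granulocytes, monocytes, stroma, endothelium and epithelium, and common reference genes, were measured the same way. Leukaemia cells can express some of these markers themselves, so a rise does not by itself show other cells in the culture. Of 19 lymphocyte markers, 0 rose and 0 fell by limma, 1 had an unadjusted p under 0.05, and 0 passed when adjusted over the list alone (camera adjusted p = 0.371). By fry the lymphocyte list did pass in 1 direction, with adjusted p = 0.0475, and not in either direction (adjusted p = 0.163). The member with the largest difference, CD4, had log2 signals of 4.17 ± 0.11 and 3.56 ± 0.77 (SD, n = 3 each; limma adjusted p = 0.267). Of 24 granulocyte and monocyte markers, 3 rose and 1 fell, and 4 passed when adjusted over the list alone (camera adjusted p = 0.972). ANPEP and CD33 rose by 3.58 ± 0.29 and 1.88 ± 0.18 on the log2 scale (SE), and LYZ, lysozyme, fell by 2.14 ± 0.19. Of 19 stromal, endothelial and epithelial markers, 3 rose and 2 fell, and 6 passed when adjusted over the list alone (camera adjusted p = 0.439). The adhesion proteins PECAM1 and ESAM rose by 2.84 ± 0.26 and 2.37 ± 0.28, and EPCAM and ACTA2 fell by 2.57 ± 0.32 and 1.51 ± 0.26. Of 14 common reference genes, 1 rose and 3 fell, and 6 passed when adjusted over the list alone (camera adjusted p = 0.439). SDHA rose by 0.83 ± 0.19, and B2M and GUSB fell by 2.08 ± 0.24 and 1.34 ± 0.18. There were 2 rises without K562 replicate 1.

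The naming rule also chose list members whose calls ended when single arrays were left out, given here with the limma adjusted p without each such array. HLA-C, an antigen-presenting chain, rose by 1.10 ± 0.30 on the log2 scale (SE), with an adjusted p of 0.0851 without K562 replicate 1, 0.0921 without K562 replicate 2, 0.0538 without K562R replicate 2 and 0.114 without K562R replicate 3. GCLM, a subunit of the enzyme of glutathione synthesis, rose by 1.42 ± 0.32 on the log2 scale (SE), with an adjusted p of 0.0536 without K562 replicate 3. CYP3A5, a drug-metabolising cytochrome, rose by 1.25 ± 0.35 on the log2 scale (SE), with an adjusted p of 0.0977 without K562 replicate 1, 0.0898 without K562 replicate 3, 0.112 without K562R replicate 1 and 0.121 without K562R replicate 3. SLC7A5, an amino acid carrier, rose by 0.86 ± 0.24 on the log2 scale (SE), with an adjusted p of 0.0846 without K562 replicate 1, 0.104 without K562 replicate 2, 0.104 without K562R replicate 1 and 0.0950 without K562R replicate 3. HSPE1, a mitochondrial co-chaperone, rose by 1.45 ± 0.41 on the log2 scale (SE), with an adjusted p of 0.120 without K562 replicate 2, 0.130 without K562 replicate 3, 0.119 without K562R replicate 2 and 0.103 without K562R replicate 3. HSPD1, its partner chaperone, rose by 1.08 ± 0.24 on the log2 scale (SE), with an adjusted p of 0.0507 without K562 replicate 3. CDT1, a replication licensing factor, fell by 0.90 ± 0.26 on the log2 scale (SE), with an adjusted p of 0.141 without K562 replicate 2, 0.107 without K562 replicate 3, 0.149 without K562R replicate 2 and 0.114 without K562R replicate 3. E2F2, a cell cycle transcription factor, fell by 0.75 ± 0.19 on the log2 scale (SE), with an adjusted p of 0.0574 without K562 replicate 1, 0.0608 without K562 replicate 3, 0.0905 without K562R replicate 2 and 0.0553 without K562R replicate 3. GABARAPL1, an autophagosome protein, fell by 1.77 ± 0.53 on the log2 scale (SE), with a difference of -2.40 without K562R replicate 1 and an adjusted p of 0.147 without K562 replicate 2, 0.151 without K562 replicate 3, 0.151 without K562R replicate 2 and 0.124 without K562R replicate 3. SOD2, the mitochondrial superoxide dismutase, fell by 0.76 ± 0.22 on the log2 scale (SE), with an adjusted p of 0.0880 without K562 replicate 1, 0.0536 without K562 replicate 2, 0.0516 without K562 replicate 3, 0.0582 without K562R replicate 1, 0.120 without K562R replicate 2 and 0.103 without K562R replicate 3.

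In 9 lists that did not pass, the median, the mean and the camera direction differed in sign. These were the STAT5 target, haemoglobin, stem cell, granulocyte, apoptosis, antigen presentation, integrated stress, hypoxia and autophagy lists. For the STAT5 targets the median was 0.03 and the mean -0.38.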

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

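Of the tests below, the bootstrap interval for the neighbours of ABL1 and BCR was chosen only after the result was seen.

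Outside the gene test, 74 transcript clusters with no or several Entrez IDs were higher in K562R than in K562 by limma and 68 were lower, of 1958. They are given here because they are a signal in data that the comparison of genes does not use. The rises ran from 0.76 to 6.52 on the log2 scale. Of the clusters that passed, 25 higher and 12 lower had no Entrez ID at all.

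The difference between the lines in 80 genes by at least 16-fold was weighed against other origins of the cells. If the K562R arrays held another line without the deletion on the short arm of chromosome 9 that K562 carries, MTAP, a gene inside it, would be higher there by more than 2 on the log2 scale. It differed by 0.27 ± 0.21 (SE; limma adjusted p = 0.479) and lay below the median of all genes in both lines, which argues against such a line. No array here shows that the MTAP probes respond, and another line with the same deletion stays open. A biological difference by the design, resistance to drugs, stays open and was not tested.

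Neighbouring genes shifted together along the chromosomes. Of 9810 windows of 30 neighbouring detected genes, 3205 had a median log2 difference beyond 0.3, against at most 284 in 100 random reorderings of the genes, as regional differences in gene dosage between the lines would give. Consecutive windows beyond 0.3 in the same direction, joined into runs, held 54.3% of the detected genes. They held 69.3% of the detected genes called at least 2-fold apart. The runs were drawn from the same differences as the calls, so a higher share of called genes in them is no separate evidence. The share in reordered genes was not computed. The runs with the highest and the lowest median are given as examples. On chromosome 3 from ALDH1L1 to FAM157A, 169 of 204 genes were higher in K562R, with a median of 0.71. On chromosome X from TCEAL8 to IL9R, 130 of 161 were lower, with a median of -0.84. Differences between single arrays along the genome are argued against, since 1 array set against its group mates gave at most 273 such windows, for K562R replicate 1. Dosage may therefore differ between the lines, but shared regulation of neighbouring genes would give the same windows, and no DNA was measured.

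ABL1 and BCR were lower in K562R, by log2 differences of -1.09 and -0.66. A lower dosage of the segments that carry them would lower their neighbours, and 42 detected neighbours had a median of -0.32 (95% bootstrap interval -0.481 to -0.155). By side, 11 of 12 and 13 of 13 neighbours of ABL1 were lower (medians -0.25 and -0.38), inside a run from ASTN2 to AK8 with 97 of 116 lower, while for BCR it was 8 of 10 on the side of lower coordinates (-0.49) and 2 of 7 on the other (0.11). Random pairs of places had a 5th percentile of -0.413, and the median of the neighbours stood at percentile 9.4 of them. By the rule fixed beforehand, a median not below that 5th percentile counts against lower dosage. The interval added later contains the 5th percentile, and the test pools both sides of each gene, which moved differently for BCR. It therefore cannot tell lower dosage from no loss for ABL1 and BCR as a pair. The BCR call also ended with each array left out, with limma adjusted p = 0.0821, 0.0567 and 0.0838 without K562 replicates 1, 2 and 3 and 0.0837 and 0.0515 without K562R replicates 2 and 3, and higher still without K562R replicate 1.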

How the results depend on the processing

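Of the alternatives, only the count over all clusters with 1 symbol was chosen after seeing the data. The count of genes differing between K562R and K562, 3035, lay between 2276 (floor at the 10th percentile) and 3618 (array weights) under the alternatives that keep the threshold and all arrays, and between 2096 and 3102 with 1 array left out. It was 1641 at an adjusted p under 0.01, by the stricter threshold itself. The count of genes differing at least 2-fold between K562R and K562, 1753, lay between 1305 and 1804, and between 1647 and 1862 with 1 array left out; it was 3014 at 1.5-fold and 420 at 4-fold, by the size threshold itself. ANGPT1 was higher by 1.15 to 1.39 under all alternatives run, with a limma adjusted p of at most 0.0150. The count of gene lists shifted between K562R and K562 was 6 or 7 under the scalings, filters, variance models and ranks. It was 5 to 8 with 1 array left out, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). For the ERK list a higher correlation does not account for that loss, since its estimate of 0.00537 lay below the preset 0.01. The estimated setting also rests on the few degrees of freedom of the 6 arrays, which makes it stricter at an equal correlation. How much of the loss in the other lists comes from each was not tested. With the replicate number as a block (replicate block), 2351 genes passed, 1647 of them at least 2-fold apart, and 6 lists; the deviations of arrays with the same number correlated at -0.234, -0.153 and -0.00587, so the numbers do not pair the arrays. STAT5B, which did not pass in any setting, turned to -0.059 with array weights and ran from -0.11 to 0.26 with 1 array left out; the cause was not tested. For 117 genes of the naming rule besides ANGPT1, 1779 of 1867 values kept their direction and side of the threshold and 85 in 21 genes no longer passed, 56 of them with 1 array left out. The floor at the 10th percentile also ended the calls of BUB1, CCL2, IL1RAP, MSMO1, PSAT1 and TNFAIP3, and the mean of a gene's clusters that of IL1RAP. For 27 genes named outside the rule, 413 of 431 values kept both, and for the lists 101 of 108. Signal over background limits the folds: of 80 genes at least 16-fold apart, 52 had a mean in the lower line below the level of 95% of olfactory receptor genes. Centring moved the median log2 difference of all genes by -0.0334.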

Other observations

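Among families of genes with a shared name root, chosen after the data were seen, the metallothioneins stood out. These genes encode small proteins that bind zinc and copper, apart from non-coding members such as MT1L. Of 13 genes, 11 rose and 0 fell (camera adjusted p = 9.50e-09 over 350 families, and 0.986 with an estimated correlation). The 10 measured MT1 and MT2 genes of chromosome 16 rose by 2.73 to 6.84 on the log2 scale. K562R replicate 3 was the lowest K562R array for each of them, and without it MT1H rose by 5.22 in place of 4.06 and MT1E by 4.33 in place of 3.24. Without K562R replicate 2 the rise of MT1H was 3.44 and that of MT1F 4.32 in place of 4.93, and without K562R replicate 1 that of MT1G was 4.25 in place of 4.96. MT1A, MT1F, MT1G and MT1M rose by 6.92, 5.79, 6.04 and 4.09 without K562R replicate 3, in place of 5.96, 4.93, 4.96 and 3.07. The 6 measured CT45A genes fell, with log2 differences of -6.51 to -3.74, while 6 of 9 SSX genes rose and 0 fell. Integrin alpha chain genes with a number after ITGA, which leaves out ITGAV, ITGAM and ITGAX, had 5 of 11 risen (camera adjusted p = 0.00878, or 0.986 with an estimated correlation). These directions held under quantile normalization and under centring. Near-identical copies share probes, so the members are not independent measurements, and 0 families passed with an estimated correlation.

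Further genes were chosen after their values were seen, with no test of them as a set. PTPRC, which encodes CD45, rose from 6.03 ± 0.52 to 12.04 ± 0.29, AIF1 from 7.48 ± 0.40 to 13.59 ± 0.20, DOCK2 from 4.20 ± 0.02 to 10.15 ± 0.40 and LAPTM5 from 11.99 ± 0.52 to 17.23 ± 0.29 (SD, n = 3 each). Beside the beta-globin cluster, OR51B4 and OR51B2 fell by 5.04 and 2.93 on the log2 scale, as OR51B5 did, while HBB and HBD rose by 1.21 and 1.60. A cluster shared by HBG2 and HBG1, outside the gene test, had signals of 17.73 ± 0.37 and 18.67 ± 0.13.

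The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3035 genes by limma, 1753 of them at least 2-fold apart, and the highest of the other splits gave 0 of each. At an unadjusted p under 0.05 the real split had 5151 genes and the others 275 to 1232. For both counts 1 of the 10 splits, the real one, gave as many. The real split gave 6 lists past camera and the other splits 1 to 5 each, so 1 of 10 gave as many lists. Camera with the preset correlation thus also called lists in splits where 0 genes passed.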
